A study of Mus musculus with 12 samples.

How the data were processed

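RNA had been sequenced from cultures of dissociated MC38 tumours, a mouse colon carcinoma model, after 6 days of treatment. The 12 samples formed 4 groups of 3: a control antibody (IgG), an antibody against PD-1 (aPD-1), the PD-1 antibody together with a CD8 antibody (aPD-1+CD8), and interferon-gamma protein (IFNg). Groups were taken from the treatment given in each sample's labels. Per the labels' protocols, RNA was isolated from lysates made inside the culture devices with a DNase step, and libraries were made from 250 ng of total RNA by exome capture. Capture measures the genes that its probes cover, and which mouse genes had probes is not given in the sources used here. Nothing in the labels says that the 3 samples of a group came from separate animals or separate cultures, so the p-values measure only the spread between these samples, which may be technical.

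The values came from 5 tables of the authors' own comparisons: aPD-1 v IgG, aPD-1+CD8 v IgG, aPD-1+CD8 v aPD-1, IFNg v IgG and IFNg v aPD-1. Per the submitters' processing notes these were made with DESeq2, whose version is not given in the sources used here, on the mm9 genome build. The aligner, the counting program, the gene annotation and the use of strand are not given in the sources used here. Per the file headers, each table holds for every gene a mean normalized count, a log2 fold change with its standard error, a Wald score, a p-value and an adjusted p-value. The mean normalized count is the authors' mean over the libraries of both groups after scaling for library size. Under 1 normalization of all 12 libraries, the mean counts of a gene in IFNg v IgG minus IFNg v aPD-1 would equal those in aPD-1+CD8 v IgG minus aPD-1+CD8 v aPD-1. Of 5706 genes with a mean count of at least 100 in every table, 5233 differed by more than 0.1% of the mean count, with a median gap of 0.647%, so the tables did not all share 1 scaling, and levels set side by side across tables are not on exactly the same scale.

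The deposited log2 fold change is that of the first named group over the second. Its standard error stayed bounded for genes with very low counts, which is how fold changes shrunken toward 0 look. The deposited fold changes are therefore taken to be shrunken, which understates the changes of genes with few counts and of comparisons with few changed genes. Under a mean count of 10 the median standard error was 0.133 in IFNg v IgG against 0.275 in aPD-1 v IgG. Values in IFNg v IgG thus appear more strongly shrunken, so sizes in these comparisons are not on the same scale. The Wald score in the deposited tables equalled the log2 fold change divided by its standard error. The deposited p-value was recomputed from that score as a 2-sided normal p, with a largest difference of 6.3e-13 in log10 p over the 5 tables. The deposited adjusted p-value was recomputed by the Benjamini-Hochberg method within 3.9e-15. An empty p-value in the authors' tables is how DESeq2 marks a gene with an outlying count, and a p-value without an adjusted one is how it marks a gene removed by its filter on low mean counts. Both kinds were kept out of the counts of changed genes.

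The tables held 0 columns of single samples. The depth of each library, the spread of single libraries, leaving out a library, other splits of the samples and a fit with a replicate block were therefore not analysed here. The sum of the mean normalized counts gives the only measure of depth, and the standard error of each fold change gives the precision. Gene symbols were used as the tables give them. Of 16399 symbols over the 5 tables, 15706 matched a symbol in the mouse annotation at hand, which is for another build than mm9 and was used for names only, so no coordinates are given. Ifng, Cd8a and Pdcd1 are not analysed here.

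A gene counted as changed when its adjusted p from the authors' DESeq2 test was under 0.05. The comparisons, the thresholds, the 31 gene lists, the rule for named genes and the alternative settings were chosen before the data were examined. The lists were: interferon-gamma response; type I interferon response; MHC class I presentation; MHC class II presentation; T and NK cell markers; cytotoxic effectors; T cell activation and exhaustion; macrophage and monocyte markers; dendritic cell markers; B cell markers; neutrophil markers; fibroblast and stroma markers; endothelial markers; epithelial and MC38 tumour markers; cell cycle; genes the study's paper is known for; stem-like and progenitor genes; TNF and NF-kB response; epithelial-mesenchymal transition; cell death; p53 targets; negative regulators of JAK-STAT; inhibitory ligands; hypoxia and glycolysis; oxidative phosphorylation; cholesterol synthesis; unfolded protein and integrated stress response; immediate early and handling stress; Wnt targets; ribosomal proteins; mitochondrial transcripts and histones. Of 606 list entries 535 matched a gene in the tables, 2 of them through an older symbol. Some genes stand in more than 1 list. Named genes were, per comparison, the 6 highest and 6 lowest log2 fold changes among changed genes with a mean normalized count of at least 50, the 4 smallest p-values per direction not already named, the 3 members with the smallest p of each list whose test passed, and a fixed set that included Tnf, Cd8b1, Cd274, Ly6a, Snai1, Birc2, Birc3 and Mki67. Some genes that the rule names are not reported here. A gene named as the member of a list that fell outside this rule was chosen after its values were seen.

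Lists with at least 3 members in a table were tested with cameraPR of limma 3.58.1 in R 4.3.3. It compares the Wald scores of the members with those of all other genes, 2-sided, with a preset correlation of 0.01 between genes. The p-values were adjusted by Benjamini-Hochberg over the 155 tests of 31 lists in 5 comparisons. Preset correlations of 0.05 and 0.1 were alternatives. An estimated correlation could not be computed, since the tables hold no values per sample. Members were counted as higher or lower over all genes and again with p adjusted over the list alone.

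Fold changes of comparisons that share a group were compared across genes by Pearson and Spearman correlation and covariance. Beside each stands the mean over 100 simulations of unchanged groups sharing the same libraries, drawn from the deposited standard errors, over all genes and over genes with a mean count of at least 100. The other alternatives were thresholds of 0.01 and 0.1 for the adjusted p, a minimum log2 change of 1, no filter on low counts, minimum mean counts of 10 and 100, an empirical null, fold changes recentred on the median of genes with a mean count of at least 100, and the indirect comparison made from the other tables. The median used for recentring was farthest from 0 in aPD-1 v IgG, at -0.0143 in log2.

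The list test and the calls were tested on simulated data for aPD-1 v IgG. Lists shifted by 1.5 on the score scale were called in 20 of 20 simulations over 15677 genes, a list shifted by -0.75 in 18 and one shifted by 0.75 in 13, and 2 of 540 unshifted lists were called. At a preset correlation of 0.05 the lists shifted by -0.75 and 0.75 were called in 6 and 7 of 20 simulations, and at 0.1 in 1 and 2. In such data a call lost at these settings does not show that a list had not shifted. The scores for these list tests were drawn independently between genes from a standard normal. The deposited scores of aPD-1 v IgG spread wider (robust SD 1.30), and the list test sets a shift against that spread. The share of shifted lists called is therefore too high for shifts of this size in the deposited scores. A list that did not pass may still have shifted. How often lists of correlated genes are called, rightly or falsely, at any of the preset correlations was not tested. Of 200 genes simulated with a log2 change of 1 among 12024 genes, 66.3% were recovered, and 4.36% of the calls were false. Computations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.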

Results

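Fresh MC38 tumours were dissociated, and the fragments of 40 to 100 µm were embedded in collagen at 2.8 mg/mL in microfluidic chips that keep small tumour pieces alive in 3 dimensions with the cells they contain. Each well received 300 µL of medium with its treatment for 6 days. The treatments were a control IgG (clone 2A3), a PD-1 antibody (RMP1-14), the same antibody with a CD8 antibody, each antibody at 10 µg/mL, and interferon-gamma at 100 ng/mL. The labels name no antibody in the IFNg wells and no control antibody beside aPD-1 alone. Comparisons with IFNg therefore also differ in the presence of antibody, and those of aPD-1+CD8 in its total amount. PD-1 is an inhibitory receptor of T cells, and CD8 marks killer T cells. The labels do not say whether the CD8 antibody removed those cells. The series title names persister cells, the tumour cells left after PD-1 blockade. Each group had 3 samples. The mean normalized counts summed to between 10292941 and 11590748 over the 5 comparisons, and the ribosomal RNA gene Rn45s held between 27.8% and 29.6% of them. The number of genes listed ranged from 15306 to 15677.

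Transcripts of lymphocytes were scarce in these cultures. Cd3e, part of the T cell receptor complex, had a mean normalized count of 0.381 and Cd8b1 one of 0.304 in the authors' deposited table of aPD-1 v IgG. Of the 44 entries of the T, NK and cytotoxic lists, 22 are not analysed here, among them Cd8a, Cd3g, Cd2, Gzma and Nkg7. Of the other 22, 14 had a mean count under 1, and 3 reached 10: Ccl5, Eomes and Tcf7, whose transcripts need not come from lymphocytes. Macrophage markers were low as well, with a median mean count of 6.42 over 23 members, of which 9 reached 10, among them Lyz2 at 70.8 and Csf1r at 23.7 in the authors' deposited table. With counts this low, changes of most lymphocyte marker genes were not detectable here, and whether few cells, depth or capture gave the low counts was not tested.

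A large part of the transcriptome differed between the aPD-1 and IgG cultures. Prg4, which encodes the lubricant proteoglycan lubricin, rose most in log2 fold change, by 5.84 ± 0.31 (SE) in the authors' deposited table of aPD-1 v IgG, with an adjusted p of 3.4e-78. The strongest evidence was for Pde4b, a phosphodiesterase that degrades cAMP, at 4.31 ± 0.17 (adjusted p = 1.9e-135), and for Socs3, a feedback inhibitor of cytokine signalling, at 4.47 ± 0.19 (adjusted p = 8.9e-121), both in the authors' deposited table. Type I interferon genes moved the other way: Ifi44 fell by 2.83 ± 0.29 in log2 and Oas2 fell by 2.24 ± 0.31, per the authors' deposited table. Matrix and fibroblast genes, hypoxia genes and targets of TNF signalling rose as lists, while cell cycle and ribosomal protein genes fell.

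In this comparison 2229 genes changed at an adjusted p under 0.05 (DESeq2), 1022 higher and 1207 lower with aPD-1. Among the largest increases in the authors' deposited table were Osbp2 at 4.60 ± 0.30, the kinin receptor Bdkrb1 at 4.42 ± 0.34 and the hydroxycarboxylic acid receptor Hcar2 at 4.34 ± 0.36. By p-value the authors' deposited table added the matrix metalloproteinase Mmp2 at 4.28 ± 0.19, Igfbp4, a binding protein of insulin-like growth factors, at 3.34 ± 0.15, the nuclear receptor Nr4a2 at 3.09 ± 0.15 and the IL-6 family cytokine Lif at 3.59 ± 0.20. Among the largest decreases were those of the migration regulator Elmo1 at -2.98 ± 0.29, Cdsn at -2.93 ± 0.29, Arap2 at -2.54 ± 0.23 and Gatm, an enzyme of creatine synthesis, at -2.52 ± 0.22, again from the authors' deposited table. Those with the smallest p in the authors' deposited table were Plk2 at -2.10 ± 0.16, Eps8 at -2.30 ± 0.19, Ttn at -2.51 ± 0.21 and Shmt2, the mitochondrial serine hydroxymethyltransferase, at -1.37 ± 0.12. The count was 707 for changes of at least 1 in log2 and 1190 against an empirical null, since the Wald scores spread wider than a standard normal (robust SD 1.30).

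**Figure D1:**
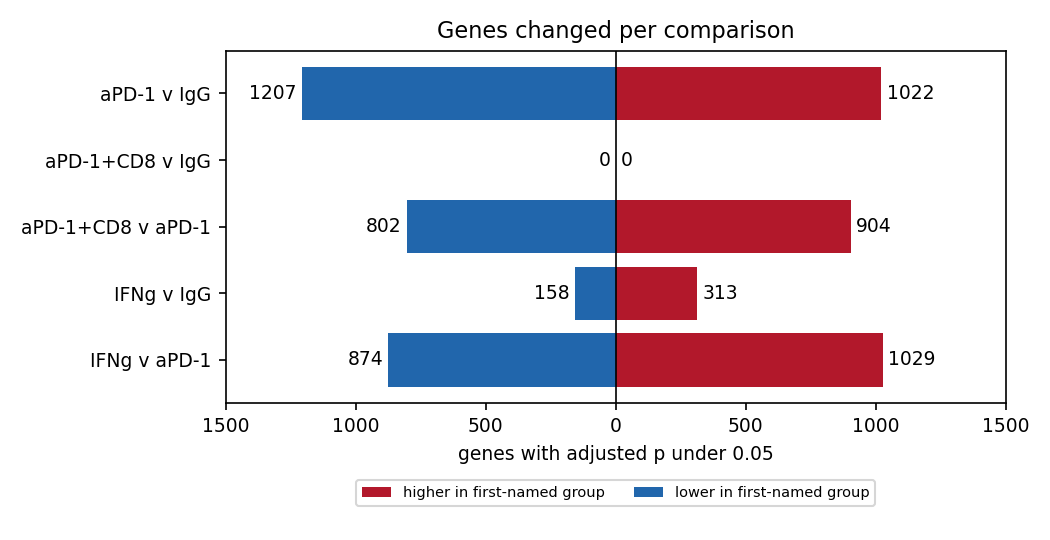
Number of genes with a deposited adjusted p under 0.05 in each of the 5 comparisons, higher (red, right) or lower (blue, left) in the first named group. With aPD-1 v IgG 1022 genes were higher and 1207 lower; with aPD-1+CD8 v IgG both counts were 0.

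The type I interferon list, antiviral genes induced by interferon-alpha and -beta, fell with aPD-1. Of its 28 listed members 26 fell and 1 rose, and the counts adjusted over the list alone were the same 26 and 1 (list test adjusted p = 3.0e-18). The cytosolic RNA sensor Ifih1 changed by -1.46 ± 0.19 and the ubiquitin-like Isg15 by -1.68 ± 0.36 in the authors' deposited table. Zbp1, a sensor of Z-form nucleic acids that can start necroptosis, was the member that rose, by 1.62 ± 0.24, and Mx1, at -0.57 ± 0.39, did not pass, in the authors' deposited table. Of the 29 interferon-gamma response genes 10 fell and 2 rose, or 11 and 3 adjusted over the list alone (list test adjusted p = 0.021). That call was lost with a preset correlation of 0.05 (adjusted p = 0.143) and of 0.1 (adjusted p = 0.322). Gbp3 at -1.65 ± 0.24 and Irf9 at -1.18 ± 0.22 fell, whereas Irf1 at 0.42 ± 0.16 and the nitric oxide synthase Nos2 at 1.64 ± 0.36 rose, in the authors' deposited table. Cd274, the PD-1 ligand, at -0.33 ± 0.40 and Tnf at 0.14 ± 0.40 did not pass (authors' deposited table).

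Fibroblast and matrix genes rose as a group. Of 20 members 11 rose and 0 fell, or 12 and 0 adjusted over the list alone (list test adjusted p = 1.2e-16). Col3a1 rose by 2.42 ± 0.19, the microfibril gene Fbn1 by 2.13 ± 0.13 and the proteoglycan Dcn by 2.09 ± 0.17, and Pdgfrb, a receptor of mural cells and fibroblasts, was at -0.28 ± 0.21 without passing, in the authors' deposited table. In the epithelial-mesenchymal transition list 9 of 22 members rose and 2 fell, or 10 and 2 adjusted over the list alone (list test adjusted p = 1.0e-12). Mmp14 rose by 1.45 ± 0.13 and fibronectin, Fn1, by 1.17 ± 0.14, while the transcription factor Snai2 at -2.05 ± 0.32 and vimentin, Vim, at -0.65 ± 0.14 fell, per the authors' deposited table. All 4 genes of the list known from the study's paper rose, over all genes and adjusted over the list alone (list test adjusted p = 3.9e-15). Its members in the authors' deposited table were the transcription factor Snai1 at 3.31 ± 0.19, the surface protein Ly6a (Sca-1) at 1.97 ± 0.32, and the inhibitors of apoptosis Birc3 at 1.71 ± 0.26 and Birc2 at 1.49 ± 0.25. That list was chosen with knowledge of the study, so its direction is not independent evidence.

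Targets of TNF and NF-kB signalling rose in 14 of 26 cases and fell in 3, or 15 and 3 adjusted over the list alone (list test adjusted p = 9.6e-14). Sod2 rose by 2.06 ± 0.15 and Nfkbiz by 1.88 ± 0.19, while the chemokine genes Ccl2 at -0.76 ± 0.27 and Ccl7 at -1.29 ± 0.41 and Tnfaip2 at -0.47 ± 0.18 fell, in the authors' deposited table. Of 21 hypoxia and glycolysis genes 11 rose and 0 fell, or 13 and 0 adjusted over the list alone (list test adjusted p = 5.9e-09), among them the growth factor Vegfa by 1.73 ± 0.15 and lactate dehydrogenase, Ldha, by 0.88 ± 0.15 in the authors' deposited table. Of 19 cholesterol synthesis genes 10 rose and 0 fell, or 13 and 0 adjusted over the list alone (list test adjusted p = 1.8e-06), with Nsdhl at 1.18 ± 0.20 and Fdps at 0.70 ± 0.14 in the authors' deposited table.

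Cell cycle genes fell in 14 of 30 cases and rose in 0, or 15 and 0 adjusted over the list alone (list test adjusted p = 2.5e-06). The members with the smallest p belonged to the start of DNA replication: Mcm2 at -1.01 ± 0.14, Mcm3 at -0.83 ± 0.14 and Cdt1 at -1.22 ± 0.21, whereas the proliferation marker Mki67 was at -0.03 ± 0.17 with an adjusted p of 0.95, in the authors' deposited table. Ribosomal protein genes, which also serve as a sign of RNA quality, moved with them: 10 of 25 fell and 0 rose, or 14 and 0 adjusted over the list alone (list test adjusted p = 1.1e-05), with Rplp0 at -0.59 ± 0.13 and Rps2 at -0.64 ± 0.15 in the authors' deposited table.

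Another 4 lists passed with members that moved both ways. The T cell activation list passed upward (adjusted p = 0.00095) with 2 of 11 members higher and 1 lower, the same adjusted over the list alone. They were Tnfrsf9 at 3.25 ± 0.29 and Nr4a2, genes that other cell types also induce, against Rgs16 at -0.82 ± 0.26, in the authors' deposited table. Its median log2 change was 0.07 and its mean 0.49, and on ranks of the score the adjusted p was 0.788. The negative regulators of JAK-STAT had 1 of 10 members higher, Socs3, and 1 lower, Usp18 at -1.33 ± 0.39 in the authors' deposited table, the same adjusted over the list alone. The test was upward (adjusted p = 0.021) with a mean of 0.27 and a median of -0.03, and it was lost at a preset correlation of 0.05 (adjusted p = 0.0614). Of 20 immediate early genes 8 rose and 3 fell, the same adjusted over the list alone (list test adjusted p = 0.0071; 0.0544 at a preset correlation of 0.05). Junb rose by 2.30 ± 0.15 and Jund by 1.11 ± 0.16, and the members that fell were Egr1 at -0.81 ± 0.20, Fosl1 at -0.90 ± 0.22 and Atf3 at -1.29 ± 0.34, in the authors' deposited table. Among 13 Wnt targets 3 fell and 1 rose, the same adjusted over the list alone (list test adjusted p = 0.034; 0.108 at a preset correlation of 0.05): Ccnd1 at -1.90 ± 0.19, Myc at -1.55 ± 0.15 and Znrf3 at -0.52 ± 0.15 against Lef1 at 0.99 ± 0.17, in the authors' deposited table.

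Members of the unfolded protein and integrated stress response list moved both ways. Of 22 members 8 rose and 11 fell, the same adjusted over the list alone, and the list test did not pass (adjusted p = 0.11). Members that rose included the mTOR inhibitor Ddit4 at 1.31 ± 0.18, the transcription factor Xbp1 at 0.88 ± 0.20 and the chaperones Calr at 1.04 ± 0.12, Pdia4 at 0.76 ± 0.14 and Hspa5 at 0.48 ± 0.13 in the authors' deposited table. Those that fell in the authors' deposited table included Herpud1, which acts in the degradation of misfolded proteins, at -0.85 ± 0.18, the transcription factor Atf4 at -0.87 ± 0.14, the enzymes Phgdh of serine synthesis at -1.62 ± 0.18 and Asns of asparagine synthesis at -1.30 ± 0.16, Trib3 at -1.79 ± 0.25 and Chac1 at -2.05 ± 0.34. These members were chosen after their values were seen.

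The other 16 lists did not pass in aPD-1 v IgG. MHC class I had 2 of 22 members higher, the chaperones Calr and Pdia3, and 3 lower, H2-K1, H2-T23 and B2m, the same adjusted over the list alone (list test adjusted p = 0.98). No member of MHC class II (10 listed, adjusted p = 0.89), of the T and NK cell markers (13, adjusted p = 0.77) or of the cytotoxic effectors (9, adjusted p = 0.51) passed, over all genes or adjusted over the list alone. Macrophage markers had 1 of 23 higher, Cd14, and 1 lower, Mertk (adjusted p = 0.30). Dendritic cell markers had 2 of 9 higher, Ccr7 and Fscn1, and 1 lower, Itgax (adjusted p = 0.50). The single changed members were Pax5, lower, of 6 B cell markers (adjusted p = 0.26), Hdc, higher, of 8 neutrophil markers (adjusted p = 0.16), Cdh5, higher, of 12 endothelial markers (adjusted p = 0.63), H2-T23, lower, of 13 inhibitory ligands (adjusted p = 0.87) and Hist1h1c, higher, of 5 histone genes (adjusted p = 0.25), where no mitochondrial transcript was used here. Epithelial markers had Ereg higher and Krt19 lower of 14 (adjusted p = 0.87), and stem-like genes had Ly6a higher and Sox2 and Itga6 lower of 16 (adjusted p = 0.24). All these counts were the same adjusted over the list alone. Of 24 cell death genes Casp1, Fas, Tnfrsf1a and Bcl2l11 rose, 4 over all genes and 5 adjusted over the list alone (list test adjusted p = 0.14). Of 17 p53 targets Fas rose and Plk2, Sesn2 and Eda2r fell, the same adjusted over the list alone (list test adjusted p = 0.20). Of 22 genes of oxidative phosphorylation Cox5a and Atp5b fell over all genes and 0 adjusted over the list alone (list test adjusted p = 0.20). Of the 31 lists 14 passed, 9 upward and 5 downward, and 10 of them held at preset correlations of 0.05 and 0.1.

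The comparison of aPD-1+CD8 with aPD-1 asked what the CD8 antibody changed under PD-1 blockade. Genes that had risen with aPD-1 were lower with the CD8 antibody: Prg4 was at -5.27 ± 0.31, Mmp2 at -4.72 ± 0.23, Osbp2 at -4.32 ± 0.32, the cytokine Il11 at -4.21 ± 0.28 and Socs3 at -4.07 ± 0.20 in the authors' deposited table. Genes that had fallen were higher, with Cdsn at 2.98 ± 0.35, Elmo1 at 2.97 ± 0.31 and Ifi44 at 2.66 ± 0.33 in the authors' deposited table. The type I interferon, cell cycle and ribosomal protein lists rose, and the fibroblast, TNF, hypoxia and cholesterol lists fell.

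In all 1706 genes changed (DESeq2), 904 higher and 802 lower with aPD-1+CD8. The others named by size or p in the authors' deposited table were Cobll1 at 2.54 ± 0.32, Fam171b at 2.38 ± 0.26, Eps8 at 2.17 ± 0.20, Ttn at 2.15 ± 0.18, Plk2 at 2.09 ± 0.22 and the amino acid transporter Slc7a5 at 1.91 ± 0.20. On the lower side the authors' deposited table had Bdkrb1 at -4.15 ± 0.36, Lif at -4.07 ± 0.23, Pde4b at -4.05 ± 0.19, Igfbp4 at -3.16 ± 0.17 and Fstl1 at -3.12 ± 0.19. The count was 1099 at an adjusted p of 0.01, 656 with a change of at least 1 in log2 and 970 against the empirical null.

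Of 28 type I interferon genes 17 were higher with aPD-1+CD8 and 1 lower, or 23 and 1 adjusted over the list alone (list test adjusted p = 3.0e-14). The exception was again Zbp1, at -2.10 ± 0.29, while Oasl2 was at 1.81 ± 0.30, in the authors' deposited table. Fibroblast genes had 0 of 20 higher and 9 lower, or 11 lower adjusted over the list alone (list test adjusted p = 2.0e-13), with Dcn at -2.14 ± 0.21, Fbln2 at -1.89 ± 0.21 and Col5a1 at -1.82 ± 0.16 in the authors' deposited table. TNF targets had 1 of 26 higher and 15 lower, or 1 and 16 adjusted over the list alone (list test adjusted p = 3.9e-15). The 4 genes known from the paper were all lower, over all genes and adjusted over the list alone (list test adjusted p = 9.2e-15, not independent evidence): Snai1 at -3.13 ± 0.23, Ly6a at -2.34 ± 0.36, Birc2 at -1.53 ± 0.22 and Birc3 at -1.20 ± 0.27 in the authors' deposited table. Hypoxia genes had 8 of 21 lower and 0 higher, or 12 and 0 adjusted over the list alone (list test adjusted p = 6.5e-08), and Vegfa was at -1.81 ± 0.18 in the authors' deposited table. Cholesterol genes had 9 of 18 lower and 0 higher, or 11 and 0 adjusted over the list alone (list test adjusted p = 8.4e-07). Mesenchymal transition genes had 8 of 21 lower and 2 higher, or 9 and 2 adjusted over the list alone (list test adjusted p = 9.7e-11). Cell cycle genes rose in 15 of 30 cases and fell in 0, or 16 and 0 adjusted over the list alone (list test adjusted p = 7.2e-07), with Mcm2 at 1.03 ± 0.17 in the authors' deposited table. Ribosomal protein genes rose beside them in 8 of 25 cases and fell in 0, the same adjusted over the list alone (list test adjusted p = 3.8e-06).

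The remaining 4 lists that passed here were weaker. The T cell activation list had 2 of 11 lower and 0 higher, Tnfrsf9 at -3.27 ± 0.32 and Nr4a2 at -3.02 ± 0.24 in the authors' deposited table, the same adjusted over the list alone (list test adjusted p = 0.0082; 0.0926 at a preset correlation of 0.1). Its median was 0.02 against a mean of -0.47. Negative regulators of JAK-STAT had Socs3 lower, 1 of 10, the same adjusted over the list alone (list test adjusted p = 0.015; 0.116 at a preset correlation of 0.1). The stress response list had 11 of 22 higher and 8 lower, the same adjusted over the list alone (list test adjusted p = 0.028 upward; 0.142 at a preset correlation of 0.05), with Phgdh at 1.62 ± 0.20, Shmt2 at 1.37 ± 0.17 and Calr at -1.22 ± 0.15 in the authors' deposited table. Immediate early genes had 3 of 20 higher and 4 lower, or 3 and 5 adjusted over the list alone (list test adjusted p = 0.041 downward; 0.161 at a preset correlation of 0.05), with Junb at -2.06 ± 0.18 in the authors' deposited table. Interferon-gamma response genes had 5 of 28 higher and 2 lower, the same adjusted over the list alone, and the list did not pass (adjusted p = 0.085). Cd274 at 0.19 ± 0.42 and Mki67 at 0.02 ± 0.19 did not pass either, in the authors' deposited table.

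**Figure D2:**
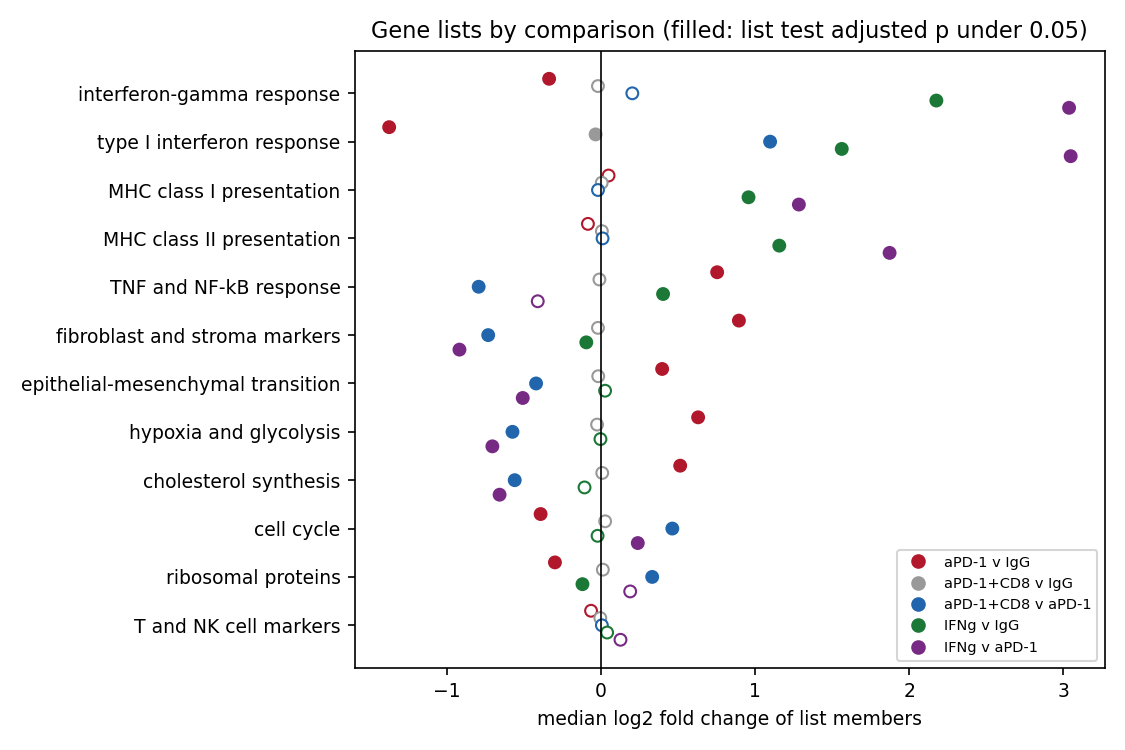
Median log2 fold change of the members of 12 gene lists (x axis) in the 5 comparisons (colours); filled points mark list tests with an adjusted p under 0.05 and open points those without. In aPD-1 v IgG and aPD-1+CD8 v aPD-1 the points lie on opposite sides of 0 for the type I interferon list, at -1.37 and 1.10.

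Between aPD-1+CD8 and IgG no gene passed. DESeq2 gave 0 changed genes at an adjusted p under 0.05, and 57 of 15304 genes had an unadjusted p under 0.05, where uniform p-values would give 765. The deposited test was therefore conservative here (robust SD of the Wald scores 0.718), and against an empirical null, which rescales the scores, the count was also 0. Ly6a was at -0.06 ± 0.06, Snai1 at 0.03 ± 0.10, Birc3 at 0.17 ± 0.10 and Mki67 at 0.00 ± 0.10 in the authors' deposited table, each with an adjusted p of 1. The largest change listed for any gene in either direction was 0.353. These fold changes and their errors appear to be shrunken more strongly than in the other tables, which the labels do not state, so their size is not set against that in the other tables. As an indirect measure, the sum of the log2 changes in aPD-1 v IgG and aPD-1+CD8 v aPD-1 was taken, which was -0.37 for Ly6a, 0.18 for Snai1, 0.51 for Birc3 and -0.0067 for Mki67. Over 6155 genes with a mean count of at least 100 its median size was 0.0709, and the 95th percentile was 0.243. An indirect value was kept for 2224 genes changed by aPD-1, which had to be listed in aPD-1+CD8 v IgG as well. Of these, 97.7% had an indirect change under 1/2 of the aPD-1 change. For the 2224 genes the median size was 0.0868 indirectly against 0.769 in aPD-1 v IgG.

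No list member changed in this comparison, over all genes or adjusted over the list alone, and 3 list tests passed. The type I interferon list was lower (adjusted p = 0.0012; 0.121 at a preset correlation of 0.1), with Cmpk2 at -0.14 ± 0.08 and Zbp1 at -0.14 ± 0.09 in the authors' deposited table and a median of -0.03, or -0.24 by the indirect measure. The epithelial list was lower (list test adjusted p = 0.0014, or 0.045 at a preset correlation of 0.1), though its members had a median mean count of 1.95. The indirect median was -0.08 over the 8 members with an indirect value. Oxidative phosphorylation was higher (adjusted p = 0.048; 0.18 at a preset correlation of 0.05), with an indirect median of 0.08.

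**Figure D3:**
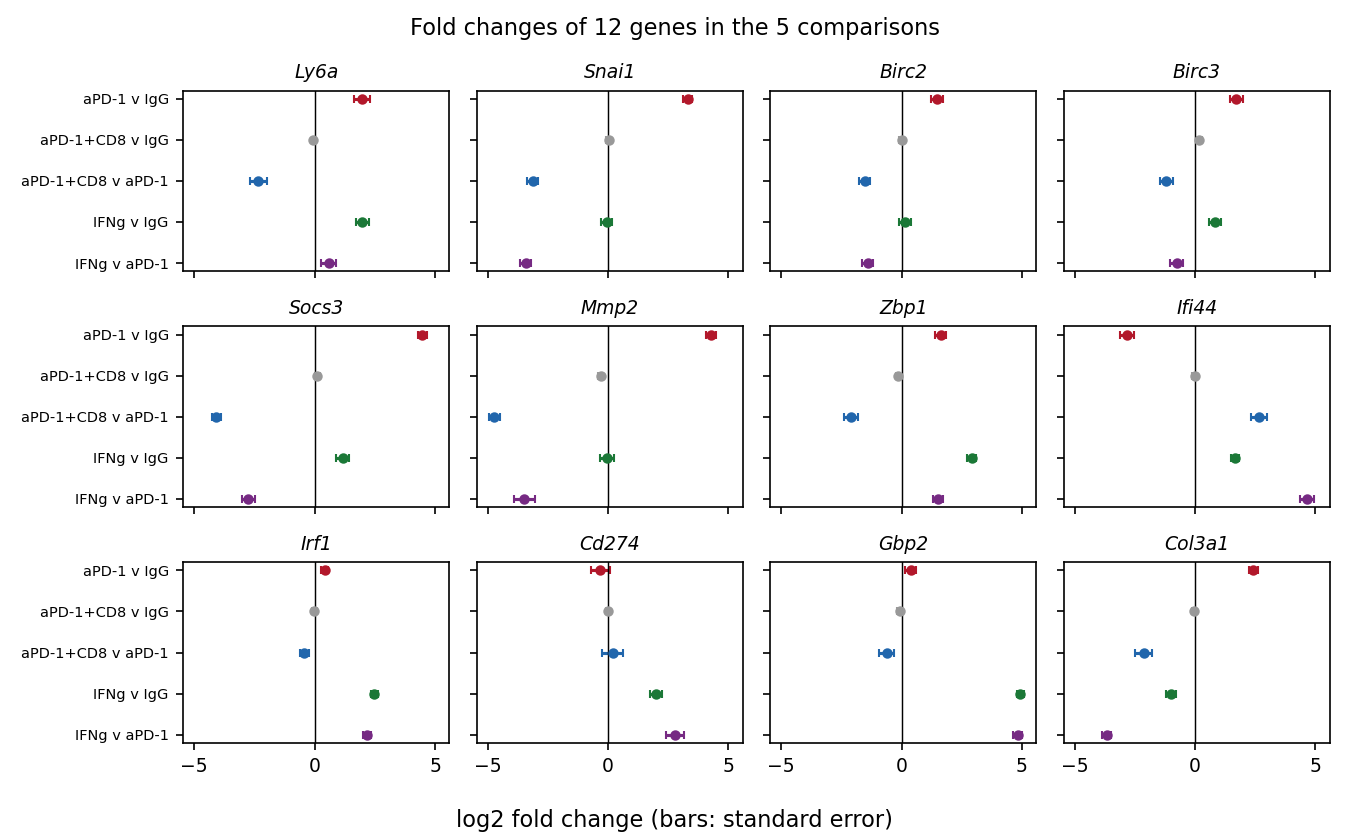
Deposited log2 fold changes (x axis, points) with standard errors (bars) of 12 genes in the 5 comparisons. Ly6a, at 1.97 with aPD-1 and 1.98 with IFNg against IgG, was listed at -0.06 in aPD-1+CD8 v IgG. Values there appear more strongly shrunken, and the indirect value was -0.37. Values in IFNg v IgG also appear more strongly shrunken than in aPD-1 v IgG, and in IFNg v aPD-1 Ly6a was at 0.58.

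The largest increases with interferon-gamma included guanylate-binding proteins and immunity-related GTPases, defence proteins against intracellular pathogens. In the authors' deposited table of IFNg v IgG, Gbp2 rose by 4.93 ± 0.16 (adjusted p = 4.4e-210), Gbp4 by 3.89 ± 0.20, Iigp1 by 3.44 ± 0.25, Igtp by 3.37 ± 0.18 and Gbp3 by 3.35 ± 0.15. The chemokine Cxcl10 rose by 3.01 ± 0.16, Irf1 by 2.48 ± 0.14 and Cd274 by 1.99 ± 0.25, also in the authors' deposited table. Antigen presentation genes of both classes rose as lists. A total of 471 genes changed (DESeq2), 313 higher and 158 lower.

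Further genes named by p in the authors' deposited table were Gbp7 at 3.11 ± 0.15 and Zbp1 at 2.91 ± 0.19, with the predicted gene Gm12250 at 3.43 ± 0.24 among the largest increases. The decreases were smaller: the adenylyl cyclase Adcy5 at -2.18 ± 0.28, the proteoglycan Cspg4 at -1.68 ± 0.23, the cholesterol exporter Abca1 at -1.54 ± 0.18, Ncam1 at -1.13 ± 0.17 and Fn1 at -0.98 ± 0.13 in the authors' deposited table. Close in size were Tnnt2 at -1.26 ± 0.26, Bhlhe41 at -1.26 ± 0.23, Pcdhb15 at -1.25 ± 0.25, Arrdc3 at -1.24 ± 0.18 and Marcks at -1.21 ± 0.16 in the authors' deposited table. With a change of at least 1 in log2, 157 genes were higher and 33 lower, 190 in all. Families such as Gbp, Ifit, Oas and H2 have close copies, and how shared reads were counted is not given in the sources used here, so values of their single members are uncertain.

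The interferon-gamma response list had 26 of 29 members higher and 0 lower, or 27 and 0 adjusted over the list alone (list test adjusted p = 4.5e-308). Type I interferon genes rose too, 26 of 28 with 0 lower, or 27 and 0 adjusted over the list alone (list test adjusted p = 5.1e-128), with Ifit3 at 2.92 ± 0.21 and Oasl2 at 2.12 ± 0.15 in the authors' deposited table. MHC class I had 15 of 22 higher and 0 lower, or 17 and 0 adjusted over the list alone (list test adjusted p = 1.1e-55). The immunoproteasome subunit Psmb10 rose by 2.25 ± 0.18, the class I transactivator Nlrc5 by 1.93 ± 0.17 and the peptide-loading chaperone Tapbp by 1.83 ± 0.16 in the authors' deposited table. MHC class II had 5 of 10 higher and 0 lower, or 7 and 0 adjusted over the list alone (list test adjusted p = 3.2e-17), led by the invariant chain Cd74 at 2.92 ± 0.25 in the authors' deposited table. TNF targets had 7 of 26 higher and 0 lower, or 10 and 0 adjusted over the list alone (list test adjusted p = 1.1e-10), with Ccl2 at 1.71 ± 0.21 and Vcam1 at 1.03 ± 0.20 in the authors' deposited table.

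Fibroblast genes were mixed, with 7 of 20 lower and 2 higher, or 7 and 3 adjusted over the list alone (list test adjusted p = 0.0015 downward; 0.0913 at a preset correlation of 0.1). Col6a2 at -1.20 ± 0.20 and Col6a1 at -1.12 ± 0.19 fell, while Dcn at 0.66 ± 0.15 and the smooth muscle actin Acta2 at 1.19 ± 0.27 rose, in the authors' deposited table. Macrophage markers stood beside them with Mrc1 at -1.29 ± 0.28 and Mertk at -0.86 ± 0.19 in the authors' deposited table, 2 of 23 lower, the same adjusted over the list alone, without the list passing (adjusted p = 0.11). Cell death genes had 2 of 24 higher, the necroptosis effector Mlkl at 0.83 ± 0.15 and the death ligand Tnfsf10 at 1.46 ± 0.28 in the authors' deposited table, or 7 adjusted over the list alone (list test adjusted p = 0.00088; 0.0913 at a preset correlation of 0.1). Inhibitory ligands had Cd274 and the tryptophan-degrading enzyme Ido1, at 1.68 ± 0.28 in the authors' deposited table, higher of 13, or 3 adjusted over the list alone (list test adjusted p = 0.0014). Without the members shared with other lists, its adjusted p was 0.446. Of the cytotoxic list only the chemokine Ccl5 rose, by 2.78 ± 0.24 in the authors' deposited table, 1 of 13, or 2 adjusted over the list alone (list test adjusted p = 0.0082; 0.112 at a preset correlation of 0.1).

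Ly6a rose by 1.98 ± 0.27 and Birc3 by 0.83 ± 0.24, while Birc2 at 0.14 ± 0.26, Snai1 at -0.06 ± 0.24, Tnf at 0.76 ± 0.27 and Mki67 at -0.16 ± 0.15 did not pass, in the authors' deposited table. With 2 of 4 higher over all genes and adjusted over the list alone, the list known from the paper passed (adjusted p = 0.0013, not independent evidence; 0.16 on ranks). Histone genes had 3 of 5 higher, or 4 adjusted over the list alone (list test adjusted p = 0.00058), with Hist1h4i at 0.75 ± 0.22 in the authors' deposited table. Ribosomal protein genes passed downward as a list (adjusted p = 0.043; 0.18 at a preset correlation of 0.05) with 0 of 25 members changed, over all genes or adjusted over the list alone. In all, 12 lists passed. Beside these values, 67 genes had no p-value in this comparison.

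The direct comparison of IFNg with aPD-1 tested where the 2 treatments differed. Interferon genes led the higher side, with Gbp4 at 5.79 ± 0.31, Iigp1 at 5.78 ± 0.35, Ifit3 at 5.66 ± 0.35 and Gbp3 at 5.23 ± 0.20 in the authors' deposited table. Prg4 at -5.98 ± 0.35, Il11 at -4.58 ± 0.30, Pde4b at -4.51 ± 0.20, Osbp2 at -4.46 ± 0.33 and Bdkrb1 at -4.28 ± 0.38 led the lower side in the authors' deposited table. Type I interferon genes were higher with IFNg in 28 of 28 cases, also adjusted over the list alone (list test adjusted p = 2.7e-105), and fibroblast genes were lower in 10 of 20 with 0 higher, or 11 lower and 1 higher adjusted over the list alone (list test adjusted p = 1.0e-22). In all 1903 genes differed (DESeq2), 1029 higher and 874 lower with IFNg, or 860 with a change of at least 1 in log2 and 1074 against the empirical null.

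The other genes named on the higher side of the authors' deposited table were AI607873 at 5.32 ± 0.28, Gm12250 at 4.95 ± 0.36, Gbp2 at 4.83 ± 0.18, Gbp7 at 3.95 ± 0.19 and the ADP-ribosyltransferase Parp14 at 3.36 ± 0.20. On the lower side the authors' deposited table had Ncam1 at -4.19 ± 0.21, Igfbp4 at -3.67 ± 0.17, Col3a1 at -3.67 ± 0.19, Snai1 at -3.42 ± 0.22 and the clock-related factor Bhlhe40 at -3.14 ± 0.17. Interferon-gamma response genes were higher in 25 of 29 cases, the same adjusted over the list alone (list test adjusted p = 4.0e-136). MHC class I had 17 of 22 higher and 1 lower, or 18 and 2 adjusted over the list alone (list test adjusted p = 1.1e-20), the exception being Calr at -0.93 ± 0.15 in the authors' deposited table. MHC class II had 5 of 10 higher, or 7 adjusted over the list alone (list test adjusted p = 3.5e-09), with Cd74 at 4.13 ± 0.34 in the authors' deposited table. Cell cycle genes were higher in 8 of 30 cases, the same adjusted over the list alone (list test adjusted p = 0.0059; 0.0732 at a preset correlation of 0.05). Ribosomal protein genes beside them had 2 of 25 higher, or 1 adjusted over the list alone, and did not pass (adjusted p = 0.057).

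Hypoxia genes were lower in 12 of 21 cases, or 14 adjusted over the list alone (list test adjusted p = 1.4e-09), with Vegfa at -2.58 ± 0.18 in the authors' deposited table. Cholesterol genes were lower in 12 of 18, or 13 adjusted over the list alone (list test adjusted p = 9.9e-07). The mesenchymal transition list had 6 of 22 lower and 2 higher, or 10 and 3 adjusted over the list alone (list test adjusted p = 1.3e-06; 0.11 on ranks), with Fn1 at -2.19 ± 0.17 and Sparc at -1.64 ± 0.17 in the authors' deposited table. Of the genes known from the paper, 3 of 4 were lower, also adjusted over the list alone (list test adjusted p = 1.2e-06, not independent evidence; 0.16 on ranks). They were Snai1, Birc2 at -1.40 ± 0.23 and Birc3 at -0.77 ± 0.28, the last with an adjusted p of 0.043 in the authors' deposited table. Birc3 in IFNg v aPD-1 had an adjusted p of 0.0548 without the filter on low counts and of 0.203 against the empirical null. Ly6a at 0.58 ± 0.31 did not differ past the threshold, and Cd274 was higher with IFNg by 2.79 ± 0.36, in the authors' deposited table. In all, 10 lists passed.

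Across 14097 genes, which are not independent replicates, the responses to aPD-1 and to IFNg against IgG had a Pearson r of 0.0844 and a Spearman rho of 0.185. Unchanged groups sharing the IgG libraries gave r = 0.565 in simulation, and the covariance was 0.0132 against a simulated 0.0366. The simulated values over all genes are too high, because for low counts the deposited standard errors exceeded the spread of the fold changes: under a mean count of 10 the median standard error was 0.275 against a robust SD of 0.183 in aPD-1 v IgG, and 0.133 against 0.0828 in IFNg v IgG. At mean counts of at least 100 in aPD-1 v IgG the robust SD, 0.369, exceeded the median standard error, 0.165. For the 6155 genes with such counts r was 0.114 against a simulated 0.497, and the covariance was 0.0171 against 0.0151. Per direction, 46 genes were higher with both treatments where independent lists would share 25.2, and 48 were lower with both against 16.7. The numbers that moved apart were 74 lower with aPD-1 and higher with IFNg, against 31.6, and 32 the other way round, against 13.3, among 11408 genes tested in both. Every one of these numbers exceeded that of independent lists, so an excess by itself does not show that the responses were alike or opposed. Of the 94 genes called in the same direction by both, 17 also differed between IFNg and aPD-1.

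The log2 changes of aPD-1 v IgG and aPD-1+CD8 v aPD-1 had r = -0.927 and rho = -0.875 across genes, where the shared aPD-1 libraries alone gave r = -0.484 in simulation. The covariance was -0.238 against a simulated -0.0365. For mean counts of at least 100, where the simulated values are less affected by low counts, r was -0.972 against -0.463 and the covariance -0.271 against -0.0153. Of the genes higher with aPD-1 726 were lower with aPD-1+CD8 v aPD-1 against 70.8 for independent lists, and of those lower 836 were higher against 94.0, with 0 in the same direction among 11539 genes. Between aPD-1+CD8 v aPD-1 and IFNg v aPD-1, r was 0.752 and rho 0.747 against a simulated r of 0.548, with a covariance of 0.239 against 0.0365. For mean counts of at least 100 this pair had r = 0.836 against 0.460 and a covariance of 0.254 against 0.0152. Over all genes tested, 571 were higher in both against 77.5 for independent lists and 543 lower in both against 60.9. The pair without a shared library, aPD-1+CD8 v aPD-1 and IFNg v IgG, had r = -0.0111 and rho = -0.0455. For mean counts of at least 100 it had r = -0.0673, rho = -0.0834 and a covariance of -0.0100 against a simulated 1.4e-05. The shared IgG and aPD-1 libraries could not be split without values per sample. They may give part of each excess in the direction that sharing favours, but not the excess of genes that aPD-1 and IFNg moved apart.

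**Figure D4:**
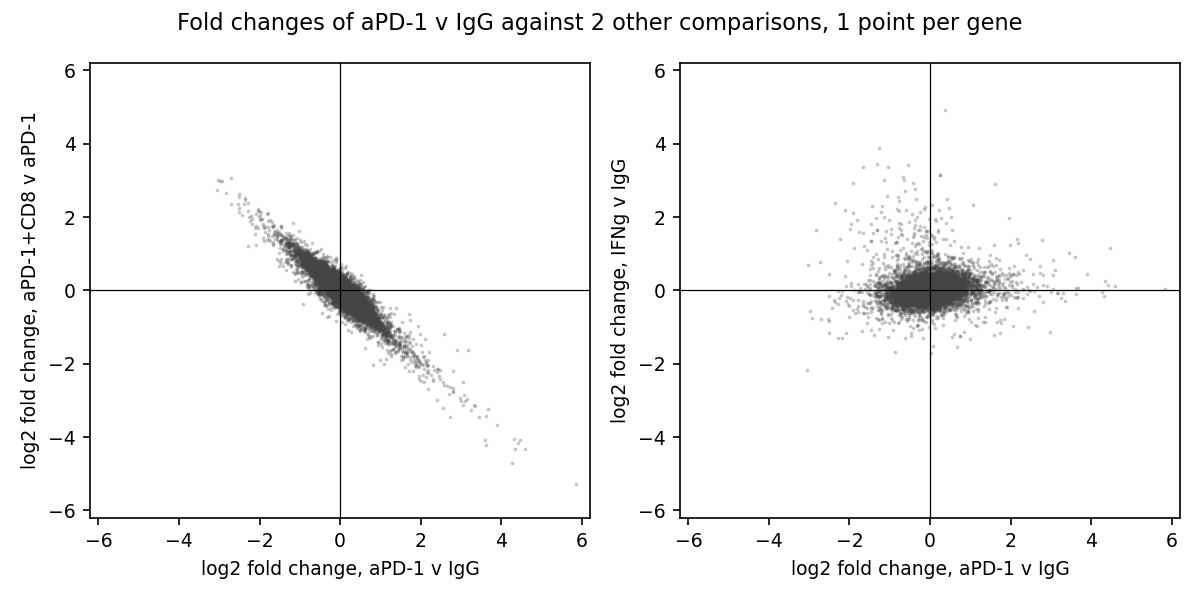
Log2 fold change of each gene in aPD-1 v IgG (x axis) against aPD-1+CD8 v aPD-1 (left) and IFNg v IgG (right), 1 point per gene over 14097 genes. The left cloud falls along a descending line (r = -0.927), in part through the shared aPD-1 libraries, and the right cloud shows little relation (r = 0.0844).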

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

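The tests of explanations in this part were chosen after the results they bear on had been seen, while the comparison of IFNg with aPD-1 was planned.

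A total of 106 genes stood out because aPD-1 and IFNg changed them in opposite directions against IgG and the direct comparison of IFNg with aPD-1 also passed (DESeq2). The direct comparison used the same aPD-1 and IFNg libraries, so it is no separate evidence for the 106 genes. Of these, 74 were lower with aPD-1 and higher with IFNg, among them the RNA-editing enzyme Adar, and 32 were the reverse, among them the cholesterol exporter Abca1. The type I interferon list stood out in the direct comparison, with 28 of 28 members higher in IFNg than in aPD-1, though Zbp1 was higher than IgG with both. The fibroblast and stroma markers stood out there with 10 of 20 lower. Against IgG, aPD-1 raised 11 of these markers and lowered 0, whereas IFNg lowered 7 and raised 2. Outside the tested values, 67 genes had no p-value in IFNg v IgG against 5 in aPD-1 v IgG.

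The first pattern weighed was that aPD-1 changed 2229 genes and aPD-1+CD8 changed 0 against the same IgG libraries, with T cell transcripts near the floor. A shift of all genes by the authors' normalization is argued against, since it would leave the spread between genes as it is. The log2 changes of 6155 well measured genes spread around their median by 2.20 times their standard errors (robust SD, bootstrap interval over genes 2.14 to 2.28). The pattern was picked for its number of changed genes, so this spread restates it. Other faults of normalization were not tested. A lower share of tumour cells was taken to raise stromal and macrophage markers alike. The fibroblast median was 1.11 (15 members) and the macrophage median -0.227 (9 members), a difference of 1.34 with a bootstrap interval over members of 0.546 to 2.27. That comparison takes the members to come from stromal cells and macrophages alone, and both cell types to last alike in culture. Neither was tested, so it cannot decide on the share of tumour cells. A growth or activation of fibroblasts themselves stays open, and so does the question of which cells gave the matrix transcripts. Handling that set the 3 aPD-1 libraries apart cannot be told apart from the treatment, because 97.7% of the calls had a difference between aPD-1+CD8 and IgG under 1/2 of the aPD-1 change and no comparison separates them. Action through CD8 T cells, the biological explanation the design names, may account for the pattern but stays open too, since the 3 lymphocyte list genes with a mean count of at least 10, Ccl5, Eomes and Tcf7, need not come from lymphocytes and so say nothing of CD8 T cells.

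The second pattern was the fall of 26 type I interferon genes with aPD-1 while Zbp1 rose. IgG libraries that stood apart are argued against, because 18 of the 27 changed members (66.7%) passed with the opposite sign in aPD-1+CD8 v aPD-1, which holds no IgG library. A shift of all genes by the authors' normalization would have moved these genes with the rest. The type I median instead lay -1.36 from that of genes with a mean count of at least 100 (bootstrap interval over members -1.64 to -1.13). The pattern was picked for this fall, so the value restates it, and other faults of normalization were not tested. Interferon-gamma released in the aPD-1 cultures is argued against at the dose tested, since IFNg raised 24 of the 26 genes (92.3%) and lowered 0, and of the 29 interferon-gamma response genes, none of them in the type I list, 2 were higher and 10 lower with aPD-1. A biological effect of aPD-1 on type I interferon signalling is a hypothesis that may explain the pattern, and handling of the aPD-1 libraries stays open as above.

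The third pattern was the number of genes without a p-value, 67 in IFNg v IgG and 43 in IFNg v aPD-1. Outlying counts in libraries of the IFNg group are a candidate explanation that the tables bear out: 39 of the 43 genes (90.7%) also lacked a p-value in IFNg v IgG. Induction that varied between the IFNg cultures stays open. Of the 71 genes without p in either comparison, 1.41% belonged to the interferon lists, namely Cxcl9. All 39 genes without p in both comparisons were listed higher with IFNg in both, and the direction of the other genes was not counted. A high outlying count in an IFNg library would itself give that direction, so it cannot decide the question. Cxcl1, Csf1r, Hif1a and Ptgs2 were also among the 71 genes. Which library held the outlying counts was not analysed here, and no biological explanation beyond the IFNg treatment was tested.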

How the results depend on the processing

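The settings below were planned, except for 1 alternative for aPD-1+CD8 v IgG that was chosen after seeing the data. With a minimum log2 change of 1, the number of changed genes went from 2229 to 707 in aPD-1 v IgG, from 1706 to 656 in aPD-1+CD8 v aPD-1, from 471 to 190 in IFNg v IgG and from 1903 to 860 in IFNg v aPD-1, as a stricter criterion must. An empirical null, which divides the scores by their robust SD, left 1190, 970 and 1074 in aPD-1 v IgG, aPD-1+CD8 v aPD-1 and IFNg v aPD-1, because those SDs were 1.30, 1.22 and 1.25. At an adjusted p of 0.01, aPD-1+CD8 v aPD-1 had 1099. The indirect comparison gave 908 for IFNg v IgG and 4734 for aPD-1+CD8 v IgG (2376 higher and 2358 lower). The first count rests on the deposited standard errors of IFNg v IgG. Their median was 0.185 against 0.221 in aPD-1 v IgG and 0.268 in IFNg v aPD-1, and whether this gave the higher count was not tested. The count for aPD-1+CD8 v IgG likewise rests on the deposited standard errors of that comparison, which were smaller (median 0.0968 against 0.221 in aPD-1 v IgG). With the standard errors of aPD-1 v IgG, the alternative added later, 4 genes passed. Of the counts and correlations, 48 values stayed within 1.5 times or kept their direction and 11 moved. Recentring moved little, its farthest median being -0.0143, so the values kept under it say little.

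Of the named genes, 659 values kept their direction and side of the threshold, 5 passed only under the indirect comparison and 2, both of Birc3 in IFNg v aPD-1, no longer passed. Of the list results, 211 were kept, 42 no longer passed and 1 turned: the negative regulators of JAK-STAT in aPD-1 v IgG went from an upward to a downward test on ranks (adjusted p = 0.981), since 1 large score, that of Socs3, counts as 1 rank. Of 52 list calls, 43 held at a preset correlation of 0.05, 37 at 0.1 and 38 on ranks. Among genes with a mean count of at least 10, 46 held, and without members shared between lists 47 did. Only 119 and 150 of the 155 tests could be run in these last settings, so some calls had no test there. The calls of the list known from the paper, for example, had none without shared members.

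Leaving out each replicate and other splits of the samples could not be run because the tables hold no values per sample, and 3 samples against 3 would in any case allow no share of splits under 0.05. No paired analysis was possible either, because the tables hold no values per sample, and no replicate number in the labels pairs the samples. The alternatives that need counts per sample, TMM against the size factors of DESeq2, a filter against none and limma on log values, were not run for the same reason. Mean counts near 0, as for most lymphocyte genes, limit what any setting can show.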

Other observations

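The 2 hypotheses below were formed after the genes with the largest changes had been seen, but the tests were written down before the tested genes were looked at, and the genes that prompted them were left out of the tested lists.

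Counts of common epithelial markers were low and those of several mesenchymal genes high, though levels of different genes also depend on the capture probes, which are not given in the sources used here. In the authors' deposited table of aPD-1 v IgG the mean normalized count was 0.152 for Epcam, 2.49 for Krt8 and 0.662 for Krt18, against 21899 for Vim, 9925 for Zeb2 and 4807 for Prrx1. The neural and stem cell factor Sox2 had 939 and the muscle gene Ttn 1289 in the authors' deposited table. Among stromal markers Col1a1 had a mean count of 1606 and Col1a2 of 13.5 in the authors' deposited table, with Acta2 at 3.40, Postn at 1.59 and Lum at 1.55. These genes were chosen after their values were seen.

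Pde4b, Nr4a2, Nr4a3, Rgs2 and Crem, all known to respond to cAMP, rose with aPD-1, with Nr4a3 at 3.62 ± 0.30, Rgs2 at 2.80 ± 0.27 and Crem at 2.19 ± 0.28 in the authors' deposited table. A wider rise of cAMP and CREB targets was the hypothesis, tested on 12 other targets. Their median log2 change was 0.31, at the 98.5th percentile of 10000 random lists matched on mean count, above the 95th percentile set as the bound. Nfil3 at 1.18 ± 0.31 and Gem at 0.96 ± 0.29 rose, and Dusp4 at -1.47 ± 0.32 fell, in the authors' deposited table. With 4 of 12 higher and 3 lower, a general rise of cAMP signalling may explain part of the pattern at most.

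Socs3, Lif, Il11, Osmr and Cebpd, genes of the IL-6 cytokine family or induced by it, rose with aPD-1, with Cebpd at 3.66 ± 0.29 and Osmr at 2.48 ± 0.24 in the authors' deposited table. The hypothesis of a wider rise of IL-6 family and STAT3 targets was tested on 17 other genes. Their median of 0.84 lay at the 100th percentile of the random lists, with 9 higher and 0 lower. Stat3 itself rose by 1.92 ± 0.15, Cebpb by 1.72 ± 0.15 and Hp by 2.10 ± 0.42 in the authors' deposited table. The values are consistent with STAT3 signalling in the aPD-1 cultures, as a hypothesis found and tested on the same libraries, and handling of those libraries stays open.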
